A study of Akebia trifoliata with 9 samples.

How the data were processed

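Leaves of Akebia trifoliata were profiled by RNA sequencing in 9 libraries, 3 each from plants given distilled water (Control), simulated acid rain of pH 2.0 without curcumin (CUR0), and the same acid rain with curcumin at 50 µmol/L (CUR50). Per the labels' protocols, the curcumin solution was given to the roots and the acid rain was sprayed on the leaves for 28 days, and the series' design text calls the 3 libraries of a group biological replicates. The labels' growth protocol gives a number of plants per treatment that differs from its number of replicates, so whether each library is a separate plant is unclear. The SDs and p-values measure the spread between libraries, part of which may be technical. The labels give no library batch, sequencing date or solvent of the curcumin.

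The authors deposited TPM values, the share of each gene among all transcripts of a library after correction for length, for 82321 genes and 9 libraries. Each column summed to between 999997 and 1000003, with values rounded to 2 decimals. The submitters' processing notes name fastp, Bowtie2, RSEM and DESeq2, without versions. All 82321 identifiers have the form written by the Trinity assembler, which builds transcripts from the reads without a genome; the assembler's settings, any filter and any annotation are not given in the sources used here. Because TPM values are shares, a rise of a few abundant genes lowers all others, and reads can be divided among similar sequences of 1 assembly. The identifiers form 55661 clusters, and 11086 of the tested genes share a cluster with another tested gene. TPM values keep no read number, so the depth behind a value is unknown and no count test was possible. Each table column was assigned to the library whose title it matches; 2 Control columns lack a letter of the title. No column was left without a library.

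None of the 82321 identifiers matched the names, tags or accessions of the 32005 genes in the reference table of the Akebia trifoliata assembly ASM1797944v1, and no sequences were used here. Genes are therefore reported by identifier, without a name, function or position. The 38 gene lists (pathways, hormones, transcription factor families, cell types and quality controls) select genes by name and could not be tested, nor could sequences of other organisms be searched for.

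The main test was limma with an intensity trend (eBayes) on log2(TPM + 1), with a mean for each group and all 9 libraries in 1 fit sharing 1 spread estimate (6 residual degrees of freedom, prior 2.49). Genes needed at least 1 TPM in at least 3 libraries, which left 31754. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was taken as a change. Differences on the log2(TPM + 1) scale understate the change of genes with low values. The design had been written for counts, with this test as its form for normalized values. The identifiers singled out are, for each of the 2 main comparisons, the 2 that rose and the 2 that fell most among genes past the threshold with a difference of at least 1, a mean of at least 5 TPM in the higher group and no overlap between the groups' values. The rule also asked for an informative name, which could not be applied, and it limits the number of identifiers where genes have no names.

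On simulated data with the real means and spreads of the 31754 genes and 200 changed genes, the test recovered 42% of changes of 1 and 83% of changes of 2 on the log2 scale for CUR0 against Control. It recovered 41% and 77% for CUR50 against CUR0, and 37% and 74% for CUR50 against Control. Of the calls, 2.34%, 7.81% and 4.31% were false. The simulation gave all groups the same spread, and drew the changed genes only from those with a mean log2(TPM + 1) above 1. It changed fewer genes than were called in any comparison of the data, and the adjusted p depends on that share. These percentages therefore need not hold for the real test.

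The relation between CUR0 against Control and CUR50 against CUR0 was measured as the correlation and covariance of the differences across genes and as the number of genes called in opposite and in the same directions. It was set beside 100 simulations of unchanged groups, drawn with each gene's own spread in each group, and beside the overlap of independent lists. The gene lists, the tests, the rule for identifiers and the following alternatives were fixed before the data were examined: quantile normalization, no filter, a filter of 5 TPM, limma without the trend, only the 6 libraries compared, a replicate block, leaving out each library, a minimum difference of 1 and a pseudocount of 0.1. Alternatives added after seeing the data were median-of-ratios scaling, removal of the 10 most abundant genes, TPM summed per cluster, and array weights per group. Analyses used R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and figures used Python 3.11.15 with matplotlib 3.10.9.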

Results

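RNA sequencing was done on leaves of Akebia trifoliata, a woody vine, after 28 days of treatment. The 9 libraries fell into 3 groups of 3, which the series describes as biological replicates. Control plants were watered and sprayed with distilled water. The CUR0 plants were sprayed with simulated acid rain of pH 2.0 and received no curcumin, and the CUR50 plants received curcumin, the yellow polyphenol of turmeric, at 50 µmol/L to the roots under the same spray. Expression was given as TPM, the share of each gene among all transcripts of a library after correction for length, for 82321 genes of a transcriptome assembly, known only by assembly identifiers, of which 1839 were at 0 in every library. The number of genes above 0 TPM was 57007 ± 966 in Control, 57077 ± 1191 in CUR0 and 54712 ± 1850 in CUR50 (SD, n = 3). TPM values do not keep the number of reads, so the sequencing depth of the libraries is unknown and no counting error is attached to the values. The 31754 genes with at least 1 TPM in at least 3 libraries were tested, and they held between 98.1% and 98.6% of each library's TPM.

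On the first principal components of log2(TPM + 1) the Control libraries and the CUR0 libraries each lay together, and the CUR50 libraries did not. On the first component CUR50 replicate 2, at 16.9, fell within the CUR0 range of 12.8 to 26.9. On the third, with 13.5% of variance, CUR50 replicate 1, at 70.7, lay apart from replicates 2 and 3, at -69.0 and -49.2. Correlations across genes ran from 0.947 to 0.951 between Control libraries and from 0.944 to 0.950 between CUR0 libraries. They were lower between CUR50 libraries, from 0.895 to 0.919, and overlapped the range between CUR0 and CUR50 libraries, 0.890 to 0.926. The median gene varied with an SD of 0.18 on the log2 scale within Control, 0.21 within CUR0 and 0.32 within CUR50. No library held the same values as another. The most abundant gene of the assembly, TRINITY_DN54103_c1_g1, chosen after its values were seen, took 8.61% ± 0.61 of all TPM in Control, 12.2% ± 1.4 in CUR0 and 7.50% ± 2.21 in CUR50 (SD, n = 3). None of the comparisons of this gene passed the threshold (limma, adjusted p = 0.440 for CUR0 against Control, 0.241 for CUR50 against CUR0 and 0.706 for CUR50 against Control).

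**Figure D1:**
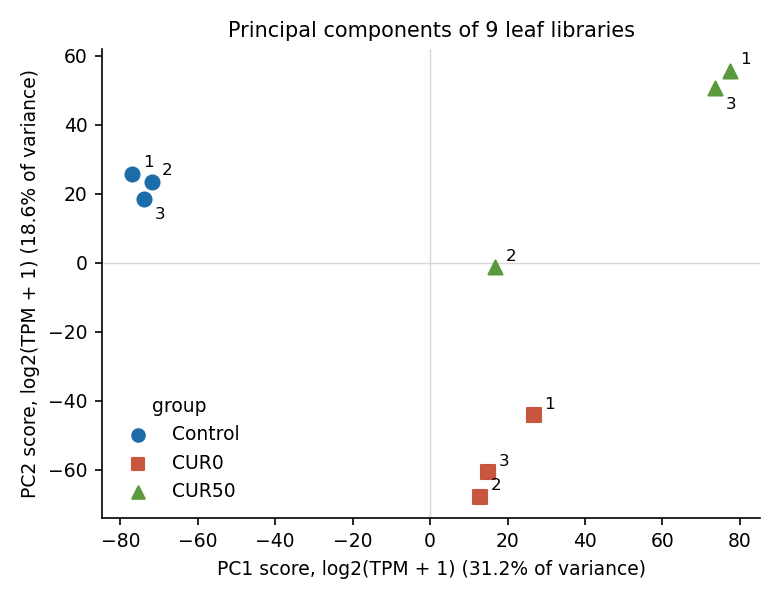
Scores of the 9 leaf libraries on the first 2 principal components of log2(TPM + 1) over the 31754 tested genes, with the share of variance on each axis (31.2% and 18.6%); each point is 1 library, numbered by replicate. The Control libraries lie together, from -76.9 to -71.9 on the first axis, and CUR50 replicate 2, at 16.9, lies apart from CUR50 replicates 1 and 3, at 77.4 and 73.6.

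The first comparison, CUR0 against Control, addresses what simulated acid rain changed in the leaves. Of the tested genes, 2622 (8.26%) changed, 940 upward and 1682 downward (limma, Benjamini-Hochberg adjusted p under 0.05). The median change was 1.39 on the log2(TPM + 1) scale among the genes that rose and -1.11 among those that fell, and 657 and 945 of them changed by at least 1 on this scale. Summed over genes, those that rose made up 1.72% ± 0.06 of all TPM in Control and 3.94% ± 0.07 in CUR0 (SD, n = 3). The genes that fell made up 6.93% ± 0.10 in Control and 3.69% ± 0.19 in CUR0. In the CUR50 libraries, which are in neither of the groups compared, these genes made up 3.94% ± 0.13 and 4.52% ± 0.20. The genes were chosen on the Control and CUR0 libraries, so their shares there are not independent of the calls. The CUR50 libraries entered the choice through the shared spread estimate, which favours genes that vary little within CUR50. Of the 1020 genes with a mean of at least 100 TPM, 14.8% changed, 62 upward and 89 downward, a balance that turned to 89 upward and 76 downward with quantile normalization and to 107 and 60 with median-of-ratios scaling. Without regard to the model, the 3 CUR0 values lay all above or all below the 3 Control values in 35.9% of the tested genes. Chance gives 10% for any 1 gene. A shift shared by the genes of a library can move this share, which was not recomputed after scaling.

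The identifiers singled out by the rule fixed beforehand are the extremes of 826 genes that met its conditions, and their changes are not typical. TRINITY_DN6111_c0_g1 rose from 2.17 ± 1.01 TPM in Control to 399.5 ± 89.9 TPM in CUR0 (SD, n = 3), a difference of 7.02 ± 0.84 (SE) in log2(TPM + 1) with a limma adjusted p of 0.00253. TRINITY_DN7407_c0_g2 was listed at 0 in Control replicates 1 and 2 and at 1.27 TPM in replicate 3, and rose to 136 ± 17 TPM in CUR0 (adjusted p = 0.000228). Its assembly cluster holds 2 genes, so its reads may have been divided with a similar sequence. TRINITY_DN13697_c0_g1 fell from 277 ± 58 to 4.20 ± 3.71 TPM, a difference of -5.97 ± 0.80 (SE) in log2(TPM + 1) with an adjusted p of 0.00411. TRINITY_DN12491_c0_g1 fell from 91.4 ± 43.6 to 0.397 ± 0.516 TPM (adjusted p = 0.000498). No gene name is attached to any of these identifiers, so what they encode is not stated here.

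The excess of genes that fell depended on the scaling. With median-of-ratios scaling, 1412 genes rose and 1412 fell, and with quantile normalization 1406 rose and 1625 fell. The total fell to 1398, 1251 and 1291 genes without Control replicate 1, 2 or 3, and to 1304 and 1153 without CUR0 replicate 2 or 3. It rose to 4117 without CUR50 replicate 1, and to 4841 when the CUR50 libraries were left out of the fit.

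**Figure D2:**
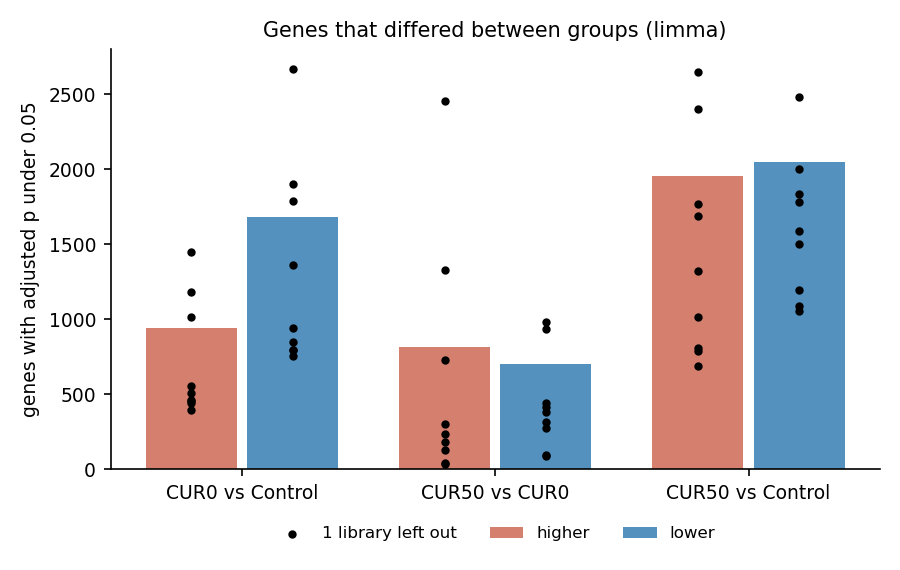
Number of genes with a limma adjusted p under 0.05 that were higher or lower in the first-named group of each comparison (bars, all 9 libraries) and the same number with each of the 9 libraries left out in turn (points). In CUR50 against CUR0 the bars stand at 816 and 700 genes and the points spread most widely for their size, with totals from 127 to 3436.

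The second comparison, CUR50 against CUR0, addresses what curcumin changed under acid rain. Here 1516 of the 31754 genes (4.77%) changed, 816 upward and 700 downward (limma, adjusted p under 0.05). The test assumes the same spread in all groups, but the median SD was 0.32 within CUR50, against 0.18 within Control and 0.21 within CUR0. The p-values of this comparison may therefore be too small. With only the 6 libraries compared 185 genes passed, and with array weights per group 508. The changes that went up were smaller, with a median of 0.73 in log2(TPM + 1), than those that went down, with a median of -1.03. The genes that rose made up 2.10% ± 0.23 of all TPM in CUR0 and 3.75% ± 0.39 in CUR50 (SD, n = 3), and those that fell made up 6.54% ± 0.35 and 3.96% ± 0.19. Among genes with a mean of at least 100 TPM, 45 rose and 112 fell. More genes fell than rose in this class also with quantile normalization (44 and 137), median-of-ratios scaling (33 and 113) and removal of the 10 most abundant genes (41 and 141). Among genes with a mean of 10 to 100 TPM, 518 rose and 270 fell, a balance that turned to 235 and 585 with quantile normalization, 303 and 427 with median-of-ratios scaling and 404 and 433 without the 10 most abundant genes. In 25.4% of the tested genes the CUR50 values lay all above or all below the CUR0 values, against 10% by chance for any 1 gene. Shifts shared by the genes of a library can move this share. The median difference of all tested genes was 0.12 in log2(TPM + 1) with the values as deposited, and the share was not recomputed after scaling.

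By the same rule, TRINITY_DN5891_c0_g1 rose from 3.71 ± 3.10 TPM in CUR0 to 75.6 ± 31 TPM in CUR50 (SD, n = 3), a difference of 4.15 ± 0.43 (SE) in log2(TPM + 1) with a limma adjusted p of 0.00556; its mean in Control was 0.180 TPM. TRINITY_DN5463_c0_g2 rose from 0.933 ± 0.869 to 24.8 ± 3.3 TPM (adjusted p = 0.00247), where Control was at 29.7 ± 5.9 TPM, and its assembly cluster holds 3 genes. TRINITY_DN6111_c0_g1, which had risen under acid rain, fell from 399.5 ± 89.9 TPM in CUR0 to 11.8 ± 16.3 TPM in CUR50 (adjusted p = 0.0145). TRINITY_DN30556_c0_g1 stood at 44.9 ± 16.6 TPM in CUR0 and was listed at 0 in all 3 CUR50 libraries (adjusted p = 0.00190); in Control it stood at 14.1 ± 8.7 TPM. The fall of TRINITY_DN6111_c0_g1 lost its call without CUR0 replicate 2 or 3 and with only the 6 libraries compared, where the highest adjusted p was 0.0786.

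**Figure D3:**
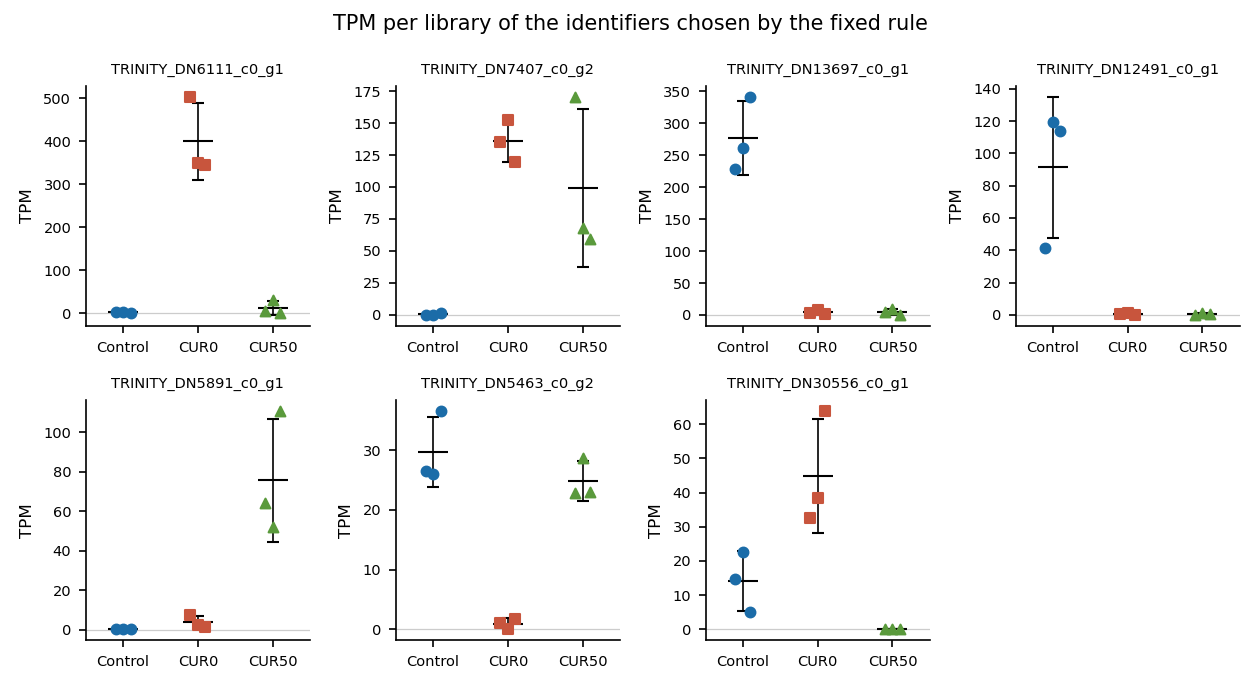
TPM of each library (points), with the group mean and SD (bars, n = 3), for the 7 identifiers chosen by the fixed rule in the 2 main comparisons; each panel has its own linear axis. TRINITY_DN6111_c0_g1 is between 345 and 503 TPM in CUR0 and at 30.5 TPM or less in every Control and CUR50 library, and TRINITY_DN30556_c0_g1 is at 0 in all CUR50 libraries.

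Relative to its size, the number of changed genes varied more between settings here, from 127 to 3436, than in CUR0 against Control, from 1153 to 5104, or CUR50 against Control, from 1744 to 4883. It was 185 with only the 6 libraries compared, where 53 genes rose and 132 fell, and 231 with the replicate block, where 68 rose and 163 fell. It dropped to 127 and 133 without CUR0 replicate 2 or 3, to 404 without CUR50 replicate 3, and to 744, 496 and 614 without Control replicate 1, 2 or 3, which enter only through the shared spread; it rose to 3436 without CUR50 replicate 1. The balance of directions turned in several settings. More genes fell than rose without the filter (181 up, 326 down), without the trend (253 and 407), with array weights (200 and 308), among differences of at least 1 (270 and 357), and without any 1 Control library, as in 184 up and 312 down without replicate 2. The excess of genes that rose was larger with the filter of 5 TPM (1589 up, 728 down), without CUR50 replicate 1 (2457 and 979) or 2 (1328 and 936), and without CUR0 replicate 1 (727 and 412). It turned with the scaling too: the median of all tested genes was 0.12 in log2(TPM + 1) with the values as deposited and 0.01 with quantile normalization, which gave 480 genes up and 1128 down. Median-of-ratios scaling gave 516 up and 954 down, and removal of the 10 most abundant genes gave 663 up and 968 down.

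The third comparison, CUR50 against Control, takes acid rain and curcumin together. In it 4007 genes (12.6%) changed, 1958 upward and 2049 downward, with medians of 0.97 and -1.11 in log2(TPM + 1) (limma, adjusted p under 0.05). The genes that rose made up 5.07% ± 0.17 of all TPM in Control, 7.42% ± 0.40 in CUR0 and 10.7% ± 0.9 in CUR50 (SD, n = 3). Those that fell made up 10.7% ± 0.5, 8.44% ± 0.40 and 6.04% ± 0.41. Of the 1020 genes with a mean of at least 100 TPM, 26.7% changed. The CUR50 and Control values did not overlap in 32.0% of the tested genes, against 10% by chance for any 1 gene. Shifts shared by the genes of a library can move this share too. The balance of directions turned to 2647 up and 2004 down without CUR50 replicate 1 and to 1889 and 1457 with the filter of 5 TPM, and was 1847 and 2566 with quantile normalization. The count was 2008, 1872 and 1744 without Control replicate 1, 2 or 3 and 2518 without CUR50 replicate 3. The 4007 genes exceeded the 2622 genes of CUR0 against Control in the shared fit. The order was the other way without CUR50 replicate 3 (2518 against 2808 genes) and with array weights per group (3295 against 5104). With only the 6 libraries of each comparison it was also the other way, 2416 against 4841 genes.

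Genes that changed under acid rain alone were compared with those that changed under acid rain with curcumin. Of the 2622 genes that changed in CUR0 against Control, 1427 (54.4%) changed in the same direction in CUR50 against Control, 438 upward and 989 downward, and 6 changed in the opposite direction. The 438 genes made up 0.879% ± 0.046 of all TPM in Control, 2.37% ± 0.06 in CUR0 and 2.99% ± 0.12 in CUR50, and the 989 genes made up 3.40% ± 0.08, 1.63% ± 0.06 and 1.67% ± 0.14 (SD, n = 3). Independent lists of these sizes would share 166 genes in the same direction, and simulated unchanged groups with the same Control libraries shared 0.11 on average over 100 simulations. Unchanged groups give almost no calls, so the latter number does not measure what the shared Control libraries add where genes do differ. The number for independent lists may be too low. Both comparisons share 1 spread estimate, and in both, genes with a mean of at least 100 TPM were called most often. The covariance of the log2 differences was 0.343 against 0.0663 in the simulations, a difference of 0.277. With 3 Control libraries the controls could not be split into separate sets of at least 2, so part of the excess may come from the shared libraries. The count was 806, 740 and 728 without Control replicate 1, 2 or 3, and 877 and 764 without CUR0 replicate 2 or 3. With only the 6 libraries of each comparison it was 1183 of 4841 genes.

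A smaller set, 395 genes (15.1% of the 2622), changed under acid rain and changed in the opposite direction with curcumin. Of these, 232 rose in CUR0 against Control and fell in CUR50 against CUR0, and 163 did the reverse. This balance turned to 135 and 293 with the filter of 5 TPM, to 353 and 548 without CUR50 replicate 1 and to 154 and 168 without CUR0 replicate 1, and was 330 and 99 with quantile normalization. The 232 genes made up 0.368% ± 0.014 of all TPM in Control, 0.788% ± 0.020 in CUR0 and 0.356% ± 0.019 in CUR50, and the 163 genes 0.606% ± 0.013, 0.349% ± 0.023 and 0.575% ± 0.025 (SD, n = 3); these genes were chosen on the same libraries. Of the 395 genes, 370 did not pass the threshold in CUR50 against Control, 19 still differed from Control in the direction of CUR0, and 6 differed from it in the other direction. In both comparisons 39 genes changed in the same direction, 22 upward and 17 downward. Without CUR50 replicate 1 or 2 this count was 116 and 121, beside 901 and 473 in opposite directions. Without CUR0 replicate 2 or 3 it was 3 each time, beside 73 and 72. Another 1082 genes changed in CUR50 against CUR0 without a call in CUR0 against Control.

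Both comparisons use the CUR0 libraries, so some opposition arises by chance. Simulated unchanged groups sharing CUR0 gave 0.12 genes in opposite directions on average, at most 2 in 100 simulations. As such groups give almost no calls, this does not measure what the shared CUR0 libraries add to the 395. Independent lists would give 63.9 in opposite directions and 61.2 in the same. These numbers may be too low, as both comparisons share 1 spread estimate and abundant genes were called most often in each. Across all tested genes, which are not independent replicates, the correlation of the 2 sets of differences was -0.31, against -0.42 in the simulations. The covariance was -0.127 against -0.0680 in the simulations, whose values ran from -0.0728 to -0.0639, and the difference was -0.0591. The 3 CUR0 libraries are too few to split, so part of the opposite calls may come from the shared libraries, and how many is not known. The count of 395 fell to 206, 159 and 189 without Control replicate 1, 2 or 3, and to 73 and 72 without CUR0 replicate 2 or 3. It fell to 186 without CUR50 replicate 3 and rose to 901 without CUR50 replicate 1. The count also rests on the spread estimate shared by all groups. It was 83 with only the 6 libraries compared, 218 with array weights per group and 100 with the replicate block.

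**Figure D4:**
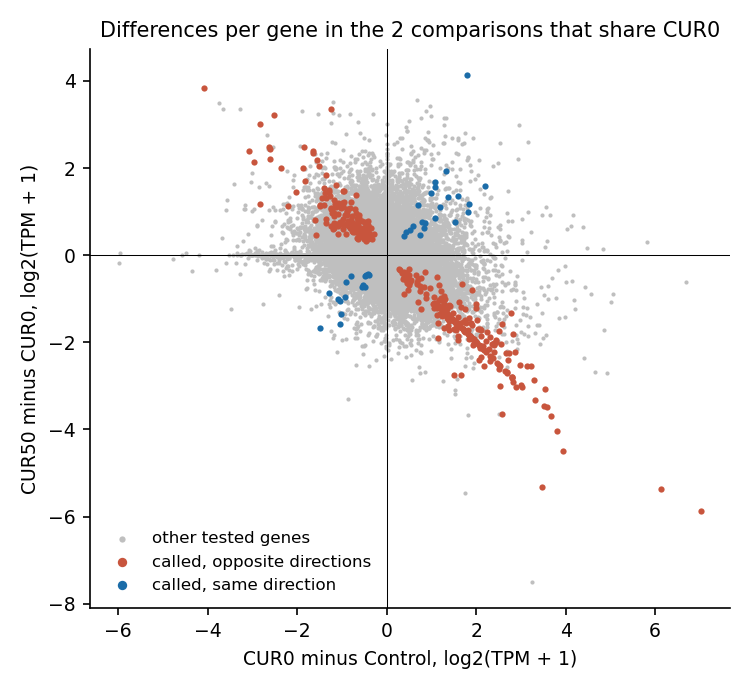
Difference in log2(TPM + 1) per gene between CUR0 and Control (horizontal) and between CUR50 and CUR0 (vertical) for the 31754 tested genes, 1 point per gene. The 395 genes called in opposite directions lie in the upper left and lower right, against 39 called in the same direction.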

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

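Median-of-ratios scaling, removal of the 10 most abundant genes, TPM summed per cluster and array weights per group were tests chosen after seeing the data. Leaving out 1 library at a time gave from 1153 to 4117 genes for CUR0 against Control, from 127 to 3436 for CUR50 against CUR0, from 1744 to 4883 for CUR50 against Control, from 72 to 901 for genes called in opposite directions, and from 728 to 1838 for genes called the same way in both comparisons with Control. The correlation of differences ran from -0.38 to -0.23. Unchanged groups that share the CUR0 libraries gave -0.42, so a negative sign arises without any reversal and says nothing about stability. Fitting only the 6 libraries compared gave 4841, 185 and 2416 genes in the 3 comparisons, and 83 in opposite directions. Array weights per group gave 5104 for CUR0 against Control, 508 for CUR50 against CUR0 and 218 in opposite directions. For CUR50 against CUR0, no filter gave 507 genes, the filter of 5 TPM 2317 and limma without the trend 660, and no filter or no trend gave 204 and 247 genes in opposite directions. A minimum difference of 1 left 1602, 627 and 2103 genes, 232 in opposite directions and 915 the same way. The correlation was -0.27 with the filter of 5 TPM, -0.37 with a pseudocount of 0.1 and -0.68 among the genes with a difference of at least 1 in both, for which unchanged groups were not simulated. The replicate numbers gave no clear pairing of the libraries, and 2 of 9 libraries were closest to their own number. Deviations from the group mean correlated from -0.04 to 0.09 between libraries with the same number and from -0.06 to 0.04 with different numbers. The highest value, 0.09, was between replicate 1 of CUR0 and of CUR50, so a weak link there is not excluded. With the replicate block, CUR50 against CUR0 gave 231 genes and 100 were called in opposite directions. No gene called in a comparison was called in the other direction under any setting that tested single genes. The settings reuse the same libraries, so such a change of direction could hardly occur, and its absence is no measure of stability. Where not stated, the cause was not tested. The 8 differences of singled-out identifiers kept their direction in all 19 settings each. They were chosen for the largest differences without overlap between the groups, so a turn was hardly possible and this says nothing about stability. Only TRINITY_DN6111_c0_g1 in CUR50 against CUR0 lost its call, in 3 of the settings. The gene list tests and a test of counts beside TPM were not run, since the table holds neither names nor counts.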

Other observations

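The tests on sets of 3 libraries and on the label of CUR50 replicate 2 were chosen after their results were seen. Some genes were detected in 1 group alone. At least 1 TPM in all 3 Control libraries and 0 in all 6 others was seen for 218 genes, against 88 genes for CUR0 alone and 30 for CUR50 alone. The highest count among the sets of 3 libraries that mix groups was 30, so CUR50 did not stand out. The 218 genes had a median of 2.36 TPM, and 5 of them had a mean of at least 10 TPM, with a highest mean of 23.3 TPM. Together they made up 684 ± 88 TPM in Control (SD, n = 3). The reverse, 0 in all 3 libraries of a group and at least 1 TPM in all 6 others, was seen for 32 genes in Control, 4 in CUR0 and 12 in CUR50. Of all 84 sets of 3 libraries, 1, the Control group itself, had as many as 218 genes, and the highest other set, the CUR0 group, had 88. Any difference between the groups keeps the counts of sets that mix them low, so these counts are not a chance level. The depth is unknown, so a value of 0 may be an undetected low value.

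The 218 genes seen in Control alone were weighed against reads being split between similar genes of 1 assembly cluster. Only 5.05% of them had a cluster partner above 0 in all 6 acid rain libraries, against 35.2% of tested genes of like level in Control (26.6% to 45% in 100 matched sets), which argues against it. RNA of another organism living on the Control leaves stays open. Such RNA might raise or lower these genes together from plant to plant, but their median deviation ranged over 0.0898 log2 units between Control libraries, within the 5th to 95th percentile of 1000 matched sets, 0.0230 to 0.139, and below the 0.5 set beforehand as a sign of it. A loss of expression of these plant genes under acid rain, and a genetic difference between the plants of the groups, were not tested.

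The wide spread within CUR50 was weighed against technical explanations. The within-group variance of CUR50 was 1.88 times the mean of the other groups, and between 1.73 and 2.17 times with any 1 CUR50 library left out. Quantile normalization left it at 1.67, against a bound of 1.5 set beforehand, so the shape of the value distributions is not the whole cause. Among genes with a mean of at least 100 TPM, where counting noise is small, the ratio was 5.01, which argues against shallow sequencing as the whole cause. CUR50 replicates 1 and 3 had the fewest genes above 0 TPM, 53436 and 53867, and the next lowest library, CUR0 replicate 2, had 56031. As the depth is unknown, a part from shallower sequencing cannot be excluded. A wrong label on a CUR0 library is argued against for CUR50 replicate 2, whose mean correlation with CUR0 minus the lowest within CUR0 was -0.0220, where the range within CUR0 was 0.00578. In the other direction, this library correlated more with CUR0 (mean 0.922) than with CUR50 replicates 1 (0.895) and 3 (0.916). A difference between plants in their response to curcumin may contribute and was not tested.

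A hypothesis was tested that CUR50 leaves lie part of the way from CUR0 back to Control. Each CUR0 library was placed on a scale from the Control mean (0) to the mean of the other CUR0 libraries (1), on genes called without it, and the CUR50 libraries were placed on the same scale. CUR0 libraries lay at 0.884 ± 0.017 and CUR50 libraries at 0.713 ± 0.056 (SD, n = 3), with all 3 CUR50 libraries below all 3 CUR0 libraries. No permutation test was run, and a two-sided exact one of 3 against 3 libraries cannot give a p under 0.1. The positions were also not obtained alike. Each CUR0 library was placed on 1 scale, and each CUR50 position is a mean over 3 scales. The difference of 0.171 exceeded the range of the left-out CUR0 positions, 0.0350, which argues against the choice of genes as its whole cause, and it was 0.182 after quantile normalization. On genes that rose under acid rain CUR0 lay at 0.866 ± 0.048 and CUR50 at 0.629 ± 0.068. On genes that fell they lay at 0.910 ± 0.080 and 0.807 ± 0.083, where the libraries of the groups overlapped. Other values go both ways. The 1682 genes that fell under acid rain held 3.69% ± 0.19 of TPM in CUR0 and 4.52% ± 0.20 in CUR50, against 6.93% in Control, while the 940 that rose held 3.94% in both acid rain groups. These genes were called with all 3 CUR0 libraries, so the choice of genes alone can place CUR50 nearer to Control. By direction the shares also differ from the positions, where the gap was larger on genes that rose. Over all tested genes the mean correlation with Control was 0.904 for CUR0 and, for CUR50 replicates 1, 2 and 3, 0.868, 0.905 and 0.875. On the first principal component CUR50 replicates 1 and 3 lay farther from Control than CUR0 and replicate 2 lay within the CUR0 range. On the second, all 3 CUR50 libraries (55.7, -1.29 and 50.6) lay on the Control side of CUR0 (-67.8 to -44.3), replicates 1 and 3 past Control (18.5 to 25.8). A partial return toward Control on part of the genes is thus a hypothesis only; a lighter exposure of these plants to the spray, or a batch that followed the groups, cannot be excluded, as the labels give neither.

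Other splits of the 6 libraries of each comparison into 3 and 3 were run with the third group kept. The real split gave 2622, 1516 and 4007 genes, and the highest of the 9 other splits gave 0, 3 and 3. Each of the 9 other splits mixes the groups compared. A real difference between the groups then adds to the spread and shrinks the difference tested. Low counts there follow from any difference between the groups, whatever its cause, so they are not a chance level. In each comparison 1 of 10 splits, the real one, gave as many genes; 10 splits are too few for a share under 0.05.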
